A study of Mus musculus with 2 samples.

How the data were processed

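RNA from 2 cultures of the mouse macrophage line RAW264.7, wildtype and labelled HuR-deficient, was extracted with an organic phenol reagent, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The deposited table holds 1 column of log2 values per array, which the authors made with RMA, per the submitters' processing notes; the version, the annotation and the genome build are not given in the sources used here. RMA corrects the background, forces the arrays to the same distribution of signals by quantile normalisation and summarises the probes of each probe set by median polish, so a change in total mRNA per cell cannot be seen and weak signals are compressed. The log2 scale was inferred from the values, which ran from 0.434 to 13.77. The sorted values of the 2 columns differed by at most 0.119, and 1788 of 41345 probe sets (4.32%) held the same value on both arrays. Scanner files and detection calls were not used here, so a low signal cannot be called absent, and the number of arrays limits the precision.

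Probe sets were named from the platform's gene table: 23521 had 1 gene symbol, 1814 had several and 16010 had none. Only those with 1 symbol were used for genes. For 1082 of the 22180 genes with several probe sets, the one with the highest mean of the 2 arrays was taken. A gene passed the signal filter when the higher of its 2 values reached 4.38, the median of all named values, which left 11905 genes. No chromosomal positions are printed, since the build behind the table is not named. Gene order for a test of neighbours was taken from a RefSeq table of assembly GRCm38.p6. Only the 11829 genes that passed the filter and had a position there were kept, so neighbours are neighbours among these.

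With 1 array per group, no p-value was computed. Genes were counted at a difference of at least 2-fold (log2 1), and each gene was set beside the robust SD and the differences of the 500 genes nearest in mean signal. There were 35 gene lists, fixed before the data were examined from general knowledge. They hold 946 distinct symbols, some in several lists; 7 entries were matched through a synonym, among them Il8, which matched Cxcl15. For each list, the median difference over all measured members was ranked among 10000 random lists of the same size drawn from 20 bins of mean signal, with a fixed seed, and called apart at or below percentile 2.5 or at or above 97.5. The percentile can range from 0.005 to 99.995. Counts of members at 2-fold use the members that passed the filter.

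The rule for named genes was also fixed before the data were examined. It took Elavl1, Plk2, Ifnb1, Tnf, Il6, Cxcl10 and Ccl5, the 14 genes with the largest positive and the 14 with the largest negative difference among those passing the filter (predicted and non-coding symbols left out), and up to 2 members per list and direction, 154 genes in all. Those of lists that did not stand apart are named only in part.

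The steps were tested on simulated data made from the real signals and their local spread for this comparison, over 11905 genes. Of 100 genes set 2-fold different, 61 were counted at 2-fold or more, and of 100 genes set 4-fold different, 100 were. Genes set exactly at the threshold fall on either side of it by noise, so the 61 largely follows from that setting and gives no detection rate. Of 11705 unchanged genes, 24 were counted. The list step, run over 22180 genes with 100 lists of 20 genes, placed 4 unshifted lists outside the central 95% and found 94 lists shifted by 0.3 to be higher. The simulation used normal noise with a robust SD, which gives little weight to extreme genes, so the count of unchanged genes follows from that setting. In the real data, 4.13% of chemosensory receptor genes, which a macrophage line is not expected to express, reached 2-fold with no filter. Among the 92 that passed the filter, 5.43% did. The 24 of 11705 therefore do not give the rate of false counts here. Real arrays also differ by culture and labelling, which 1 array per group cannot show.

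The alternatives were centring on the median difference, a further quantile normalisation, removal of a loess trend on mean signal (span 0.3), averaging of probe sets, other filters and thresholds, lists limited to genes that passed the filter, unmatched random lists and list means. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.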

Results

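Messenger RNA levels were measured on 2 Affymetrix arrays, 1 from wildtype RAW264.7 cells and 1 from RAW264.7 cells labelled HuR-deficient. RAW264.7 is an established mouse macrophage cell line. HuR, encoded by Elavl1, is an RNA-binding protein that attaches to AU- and U-rich stretches of mRNAs and is known to stabilise many of them. Both cultures had received high molecular weight poly(I:C), a synthetic double-stranded RNA that stands in for viral RNA, complexed with a lipid transfection reagent for 8 hours at a stated 1 mg/ml, a dose that is copied from the labels, is high for such a transfection and could not be checked. No unstimulated culture was analysed here, so the values compare the cells labelled HuR-deficient with wildtype cells after stimulation and do not give the response to poly(I:C) itself. The 2 arrays had 41345 probe sets each, with median log2 signals of 4.08 for the wildtype array and 4.10 for the array labelled HuR-deficient, and they correlated across probe sets with a Pearson r of 0.970. There were no replicates: each value below comes from 1 array, and no significance test could be run between the conditions. A few differences are given with the spread of genes of similar signal, which is not a spread between replicates. All differences are log2 values, array labelled HuR-deficient minus wildtype array.

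The targeted gene was examined first. Elavl1 (Entrez Gene 15568) had 1 probe set, with a log2 signal of 7.68 on the wildtype array and 7.75 on the array labelled HuR-deficient, a difference of 0.07. Of the 500 genes nearest in signal, 84.6% differed by at least as much. The Elavl1 signal therefore does not distinguish the arrays. Whether the probe set lies inside the disrupted part of the gene is not given in the sources used here, so it cannot check the genotype label, and every direction below is that of the array labelled HuR-deficient. The other ELAV genes, Elavl2, Elavl3 and Elavl4, had low signals on both arrays (median 4.06 in wildtype), and Elavl2, which passed the filter on signal, differed by 0.09.

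Among 11905 genes that passed the signal filter, 105 were at least 2-fold higher and 132 at least 2-fold lower in the array labelled HuR-deficient. Of these, 7 were at least 4-fold higher and 19 at least 4-fold lower. The largest negative differences included Ccl2, a chemokine that attracts monocytes, which had a signal of 11.19 in wildtype and 6.70 in the array labelled HuR-deficient (difference -4.49, 22.5-fold lower), and Atp6v0d2, a subunit of the vacuolar proton pump (7.37 against 2.97, difference -4.40). Rgs1, a regulator of G-protein signalling, differed by -3.52, the homeobox gene Rhox5 by -3.05 and the inhibitory receptor gene Cd200r1 by -2.73. Ctla2b differed by -2.69, the C-type lectin gene Clec4a2 by -2.60, Ms4a7 by -2.56, the metalloproteinase inhibitor gene Timp1 by -2.46, the calcium-binding alarmin S100a8 by -2.27, Sirpb1c by -2.21 and Serpinb6b by -2.10. Predicted and non-coding symbols left out, the largest positive differences were those of Gstt4, a glutathione S-transferase (4.32 against 8.86, difference 4.55), and Car2, carbonic anhydrase 2 (9.52 against 12.10, difference 2.58). Klk8 differed by 2.33, Ltb, which encodes lymphotoxin beta, by 2.32, Gstt1 by 2.17, Resp18 and Ptprn by 1.93 each, Tmem176a by 1.91, Hacd2 by 1.87, Hamp, which encodes hepcidin, by 1.80, Maged1 by 1.68 and the cyclin gene Ccnd2 by 1.67. Btbd35f28 (1.84) and AY761185 (1.78) also ranked among them. Of the 105 higher genes, 50 had a wildtype signal below the filter's floor of 4.38, and of the 132 lower genes, 56 had a signal below it on the array labelled HuR-deficient. Gstt4, Resp18, Ptprn, Hamp, Maged1, Btbd35f28 and AY761185 were among the former, and Atp6v0d2, Rhox5, Cd200r1, Ms4a7, S100a8 and Sirpb1c among the latter. Their weaker signal was not shown to lie above background, so the sizes and ranks of these differences are uncertain.

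**Figure D1:**
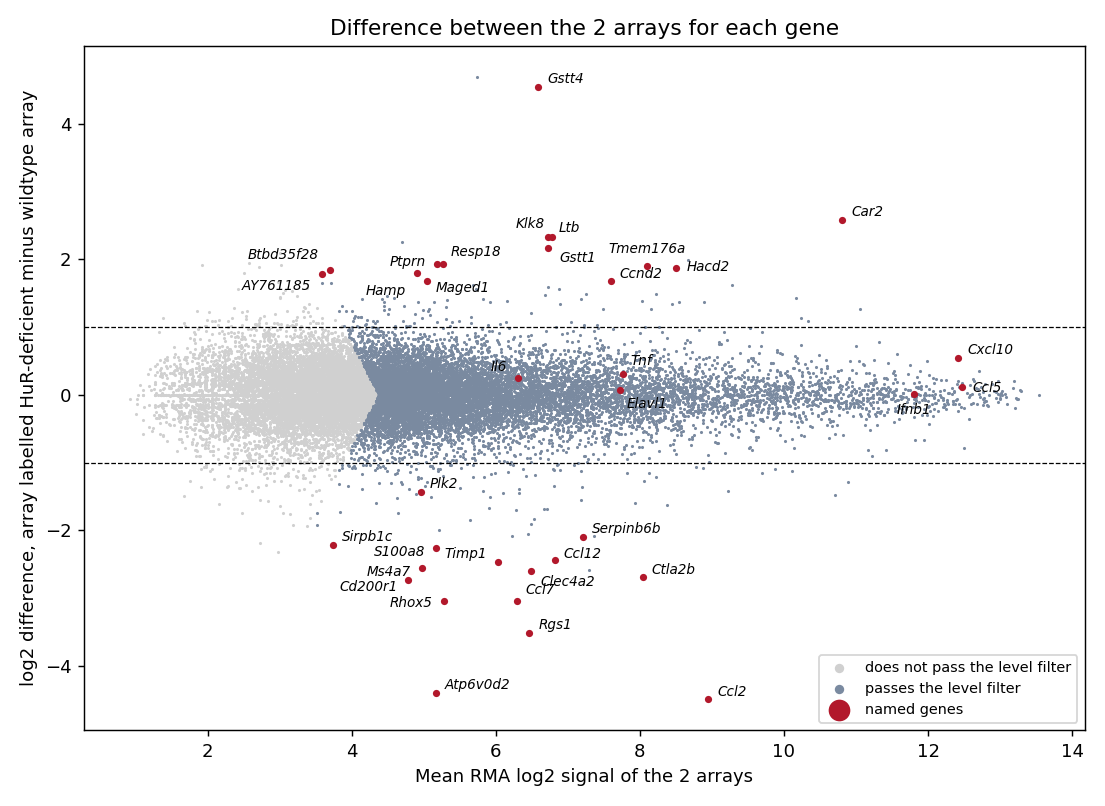
Each point is a gene, placed by the mean log2 signal of the 2 arrays (x axis) and by the log2 difference, array labelled HuR-deficient minus wildtype (y axis); dashed lines mark 2-fold. Ccl2 lies at -4.49 and Gstt4 at 4.55, while Elavl1 lies at 0.07 and Ifnb1 at 0.0050.

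Most genes differed by little: the SD of the difference over all 22180 named genes was 0.392, and 95% of the genes lay between -0.78 and 0.75. Chemosensory receptor genes, which a macrophage line is not expected to express, gave a view of noise. Of 1429 measured, with no filter applied, 26 were at least 2-fold higher and 33 at least 2-fold lower. That is 4.13%, against 1.88% of all genes. Of the 92 that passed the filter, 2 were higher and 3 lower. This share was 5.43%, against 1.99% of all genes that passed, so the filter did not remove such differences. Among all genes that did not pass, the share was 1.75%. Their median signal was 3.39, however, against 2.58 for the 1429 chemosensory genes, so low signal was not excluded as a reason for the higher share. The count of genes depended on the filter and the threshold: with no filter, 185 genes were higher and 232 lower, and at 3-fold 22 were higher and 33 lower.

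Plk2, a Polo-like kinase that is the gene of interest in the study's published work, was lower in the array labelled HuR-deficient (5.67 against 4.24, difference -1.43), where its signal was below the floor of 4.38 and not shown to lie above background. Only 0.4% of the 500 genes nearest in signal differed by as much. The other Polo-like kinase genes differed by less than the 2-fold threshold, with -0.14 for Plk3. Over all 5 measured members, Plk2 included, the median was -0.11. That median lay at the 25.8th percentile of 10000 random gene lists of the same size and signal.

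Ifnb1, which encodes interferon beta, gave a high signal of 11.80 on each array, with a difference of 0.0050. That signal lay at percentile 99.3 of all genes, and none of the 222 genes at or above the 99th percentile differed by 2-fold, so compression at the top of the scale was not excluded and the near-equal signals do not show that the mRNA levels were equal. The 18 measured type I and type III interferon genes had a median difference of -0.20, at percentile 1.23 of matched random lists, with 12 below 0 and 6 above. Ifna2 was the member at least 2-fold lower (difference -1.01), and Ifna6 (-0.55), Ifna7 (0.48) and Ifnl2 (0.17) stayed within 2-fold. Interferon alpha genes are near-identical in sequence, so their probe sets may read each other's transcripts, and the list moved inside the central 95% of random lists when the arrays were quantile-normalised again (percentile 3.33) or when its mean was used (percentile 11.004).

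Interferon-stimulated genes, the antiviral genes that interferon switches on, were slightly higher as a group in the array labelled HuR-deficient. Of 64 measured members, 52 had a positive difference and 12 a negative one, with a median of 0.18, above all 10000 random lists (percentile 99.995, the highest they can give). No member passed 2-fold: Iigp1, an interferon-inducible GTPase, differed by 0.93, Helz2 by 0.90, Ifi44l by -0.36 and Trim30a by -0.79. Cxcl10, an interferon-induced chemokine with a signal of 12.15 in wildtype, in the same top range as Ifnb1, differed by 0.55. Genes of MHC class I presentation stood in the same direction, with a median of 0.29 over 20 members (percentile 99.995) and 15 of them above 0. H2-T10 was the member past 2-fold (3.87 against 5.30, difference 1.43), from a wildtype signal below the floor, H2-T23 differed by 0.66, and the chaperone genes Canx (-0.46) and Calr (-0.44) were on the other side. The 12 measured MHC class II genes had a median of 0.25 (percentile 99.04), with no member at 2-fold, but its mean lay inside the range of random lists (percentile 97.1). Among the 8 that passed the filter, H2-Oa (0.63) and the class II transactivator gene Ciita (0.53) lay highest, and H2-DMa (-0.24) and Lgmn (-0.25) lowest. The lists for double-stranded RNA sensing (median 0.03, percentile 70.2) and interferon receptor signalling (median 0.03, percentile 67.4) lay inside the range of random lists. Within them, Mavs and Ikbke differed by 0.56 each, Tnfaip3 by -0.61 and Rnf135 by -0.39, while Il10ra differed by 0.75, Tyk2 by 0.66, Il10rb by -0.50 and Ifnar2 by -0.41.

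Inflammatory cytokine and mediator genes were higher as a group, with a median of 0.26 over 32 members (percentile 99.985). Of the 25 that passed the filter, 5 were at least 2-fold higher and 1 at least 2-fold lower. The interleukin gene Il27 was 2.81-fold higher (difference 1.49), the death ligand gene Tnfsf10 differed by 1.30 and Ptgs2, which encodes cyclooxygenase-2, by 1.15. Il10 (1.25, from a wildtype signal of 3.83, below the floor) and Saa3 (1.03), named after their values were seen, completed the 5. Il1rn, which encodes the interleukin-1 receptor antagonist, was 4.14-fold lower (difference -2.05), and Il1a differed by -0.57. Tnf (0.31) and Il6 (0.25) differed by about the robust SD of genes at their signal, 0.31 and 0.33.

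The chemokine genes divided. Ccl2, Ccl7 and Ccl12, which encode monocyte chemoattractants, were at least 2-fold lower, with differences of -4.49, -3.04 and -2.44, and no other chemokine gene passed 2-fold in that direction. Among genes that passed the filter they are neighbours in gene order, and their sequences are related. Probes shared between them were not excluded, which also holds for the Gstt, Tmem176, Clec4a and Sirpb1 genes. Cxcl9 was 2.59-fold higher (difference 1.37), Cxcl3 differed by 0.87, and Ccl5, at a signal of 12.41 in wildtype, where the limit given for Ifnb1 also holds, differed by 0.12. The list's median was 0.05 (percentile 76.6), while its mean was -0.33, below all random lists (percentile 0.005, the lowest they can give), so the direction of the whole list depends on these 3 genes.

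**Figure D2:**
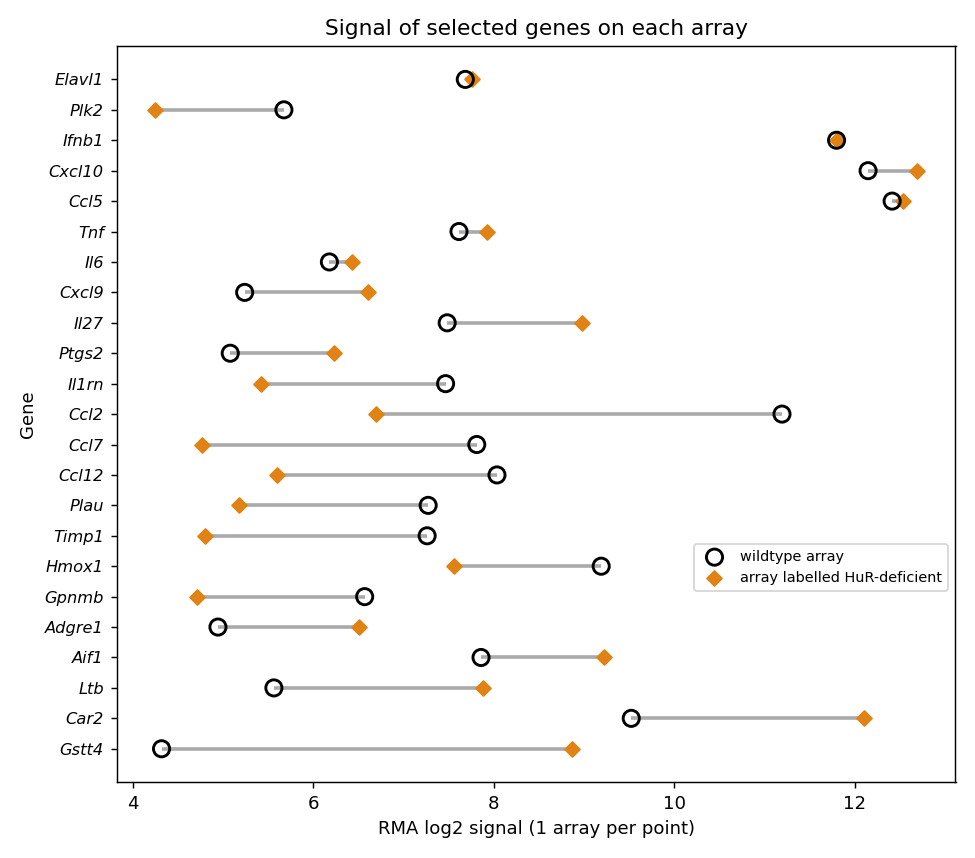
Log2 signal (x axis) of selected genes (y axis) on the wildtype array (open circles) and on the array labelled HuR-deficient (diamonds), 1 array per point. Elavl1 and Ifnb1 overlap, Ccl2 goes from 11.19 to 6.70 and Plk2 from 5.67 to 4.24.

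Genes of macrophage identity were lower as a group, with a median of -0.22 over 46 members (percentile 0.005) and 33 of them below 0. Of the 41 that passed the filter, 7 were at least 2-fold lower and 2 at least 2-fold higher. The 7 included Gpnmb, a transmembrane glycoprotein gene of macrophages and osteoclasts (difference -1.85), and the inhibitory receptor gene Pirb (-1.42). Adgre1, which encodes the F4/80 antigen, was 2.96-fold higher (difference 1.57), and Aif1 differed by 1.37. Of the markers of other cell types, 6 of 18 T and NK cell genes, 1 of 13 B cell genes, 6 of 11 dendritic cell genes, 3 of 20 neutrophil and mast cell genes and 11 of 21 fibroblast, epithelial and endothelial genes passed the filter. Their list medians were -0.04 for T and NK cells, -0.09 for B cells, 0.08 for dendritic cells, -0.15 for neutrophils and mast cells and -0.08 for fibroblasts, epithelium and endothelium, all inside the range of random lists. Among them, S100a8 was the member past 2-fold that also passed the filter.

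Genes of the oxidative stress response were lower as a group, with a median of -0.30 over 19 members (percentile 0.045), and 18 of the 19 were below 0. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, was 3.10-fold lower (9.19 against 7.55, difference -1.63), the metallothionein gene Mt2 differed by -0.91, and Blvrb, at 0.16, was the member above 0. Genes of the unfolded protein and integrated stress responses had a median of -0.14 over 33 members (percentile 1.20), with none at 2-fold, from Cebpb (-0.68) and Phgdh (-0.63) to Atf3 (0.34) and Nupr1 (0.69). Cell death genes had a median of 0.15 over 34 members (percentile 99.2), with none at 2-fold. Fas (0.97) and Bcl2a1a (0.74) lay highest, and Nlrp3 (-0.63) and Casp8 (-0.43) lowest. This list moved inside the range of random lists under 3 of the 7 alternatives tried, for example to percentile 96.99 against unmatched random lists.

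The 65 measured mRNAs that have been described as bound by HuR, collected from general knowledge of work mostly in other cells, had a median of -0.04 (percentile 22.1). Of 57 that passed the filter, 5 were at least 2-fold lower and 1 at least 2-fold higher. The lower ones were Ccl2, the urokinase gene Plau (difference -2.09), Hmox1, Plk2 and Mdm2, and Ptgs2 was the higher one. Plk2 is on the list because of the study's own published work, so it is not independent evidence there. The mean of the list, -0.17, lay at percentile 0.015 of random lists, unlike its median. A mean gives weight to extreme members, here Ccl2 (-4.49) foremost and the other lower genes named above. It therefore does not show a shift of the list as a whole, in which 40 members lay below 0 and 25 above. AU-rich element binding and mRNA decay genes had a median of 0.06 (percentile 84.6) with none at 2-fold among those that passed the filter, from Parn (-0.77) and Ybx1 (-0.55) to Exosc5 (0.53) and Zfp36l1 (0.68). NF-kappaB and immediate-early genes had a median of 0.06 (percentile 82.4), and the phosphatase gene Dusp2 was the member past 2-fold (difference 1.59), with Nfkb2 at 0.61, Dusp4 at -0.71 and Myc at -0.77.

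Growth and metabolic lists lay inside the range of random lists. The medians were -0.05 for S phase genes, -0.10 for G2/M genes, -0.10 for p53 targets, 0.02 for cholesterol biosynthesis, 0.00 for glycolysis and hypoxia, 0.07 for nuclear-encoded oxidative phosphorylation genes, 0.01 for ribosomal proteins, -0.08 for histones and -0.03 for heat shock genes. No S phase or G2/M gene passed 2-fold, with Rrm2 at -0.58 and Nuf2 at -0.66. Of the p53 targets, Plk2 and Mdm2 (-1.03) were at least 2-fold lower, while Fas and Aen (0.75) lay on the other side. Osteoclast genes had a median of -0.04 and 1 member in each direction, Atp6v0d2 lower and Car2 higher. Limited to the 11 members that passed the filter, its median was 0.28, at percentile 98.7. The list of adhesion and migration genes had a median of -0.02, with Timp1, Plau and, named after its value was seen, the integrin gene Itgb7 (-1.03) at least 2-fold lower and Timp2 higher (difference 1.12). Genes of alternative activation and lipid handling had a median of -0.13 (percentile 3.32), with Fabp4 at -0.96 and Plin2 at -0.69. Common reference genes had a median of -0.13 (percentile 5.97): Sdha and Polr2a differed by 0.04 each, while Actb differed by -0.75 and Ywhaz by -1.48, the latter by -0.66 when its 3 probe sets were averaged. In all, 9 of the 35 lists lay outside the central 95% of random lists, 5 higher and 4 lower, where 1.75 would be so by chance. Random lists take no account of genes regulated together, so these percentiles describe these 2 arrays and do not test the conditions.

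**Figure D3:**
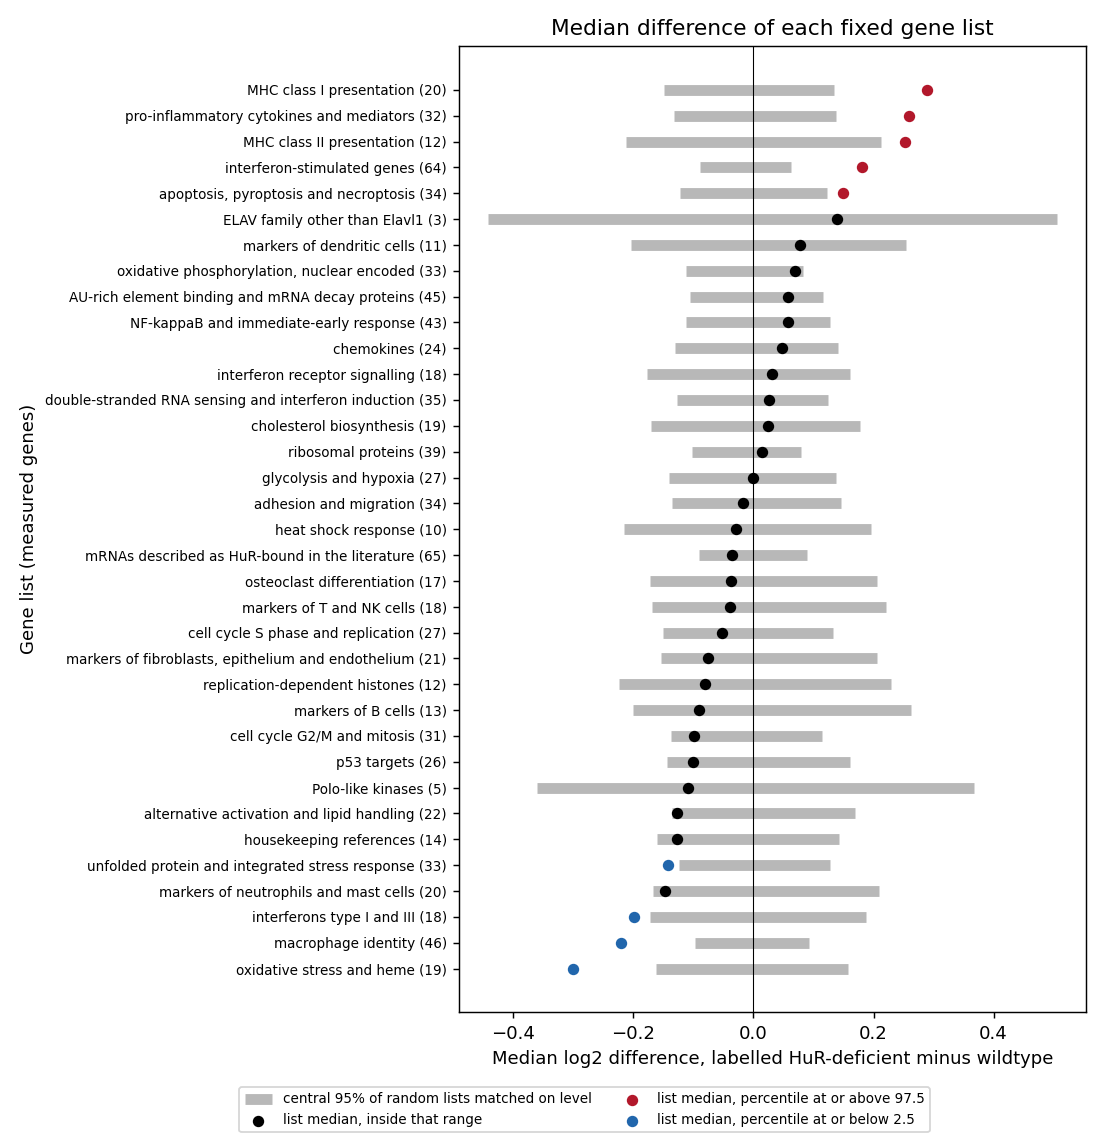
Median log2 difference, array labelled HuR-deficient minus wildtype (x axis), of each fixed gene list (y axis, measured genes in brackets); grey bars give the central 95% of 10000 random lists matched on size and signal. MHC class I genes lie highest (0.29) and oxidative stress genes lowest (-0.30).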

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

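The tests of swapped labels, of cells of 1 genotype, of a trend with signal and of stimulus strength were chosen only after the result was seen. Probe sets outside the named genes, which no comparison uses, also differed between the arrays, in both directions. Of 5726 probe sets with no gene symbol that passed the filter, 371 were at least 2-fold higher in the array labelled HuR-deficient and 392 at least 2-fold lower, which is 13.3%, against 1.99% of named genes; with no filter these shares were 11.8% and 1.88%. The largest positive difference among them was 4.75 (probe set 17549148) and the largest negative one -4.63. With 1 array per group, noise of these probe sets was not excluded, so the 13.3% does not show a change in unnamed transcripts. Of 1140 probe sets with several symbols, 10 were at least 2-fold higher and 7 at least 2-fold lower, and the largest positive difference was 2.53 and the largest negative one -2.57.

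Elavl1 was not lower in the array labelled HuR-deficient (difference 0.070). The mean signal of Elavl1 lay at percentile 90.7 of all genes, which argues only against a signal at the floor or the ceiling of the scale. Of the 500 genes nearest in signal, 2 were at least 2-fold lower. That other probe sets at this signal can differ does not show that the Elavl1 probe set responds to a loss of its mRNA, which stays open. A swap of the labels stays open, since the difference of 0.070 says nothing of it if the disruption leaves the mRNA in place. That both arrays hold cells of 1 genotype cannot be told apart from a true knockout, since the 237 genes at 2-fold have no replicate arrays to be set against. A disruption that leaves the mRNA in place, as a small coding deletion may, was not tested and stays open.

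Interferon-stimulated and MHC class I genes were slightly higher in the array labelled HuR-deficient. A trend of the difference with signal is argued against, because the trend at their members was at most 0.025 and 0.027. Once a loess trend was removed, the median of the interferon-stimulated genes went from 0.180 to 0.182 (95% bootstrap interval over genes 0.101 to 0.296). That of the MHC class I genes went from 0.289 to 0.302 (0.128 to 0.414). These intervals treat genes as independent, though they may be regulated together, and give no spread between arrays. A stronger double-stranded RNA stimulus in 1 culture would be expected to raise interferon, cytokine, chemokine and NF-kappaB lists together; only the cytokine list did so, and the interferon list lay at percentile 1.23, or up to 3.33 under another scaling. That leaves it open, because interferon mRNA may peak before the time of harvest and no unstimulated or earlier array was analysed here. The genotype named by the design stays open as well, untested beyond these 2 arrays.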

How the results depend on the processing

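No paired analysis was possible because each group has 1 array, and no array could be left out. Centring moved nothing, since the median difference was 0, so it tests nothing. The other scalings left the median of all genes within 0.1 of 0 (-0.0070 without the loess trend) and kept the direction of all 153 named genes besides Elavl1, which itself ranged from 0.07 to 0.09. Of 612 alternative values of these genes, 609 stayed on their side of 2-fold. The 612 include the centred values, and averaging of probe sets could move only the few named genes with several. Much of that agreement was therefore fixed beforehand and does not measure robustness. Fabp4 and Rps16 just reached 2-fold without the loess trend and Ywhaz lost it (-0.66) when its probe sets were averaged. Counts of genes at least 2-fold higher and lower (105 and 132) were 185 and 232 with no filter, 63 and 86 with a filter at the 75th percentile of signal, 648 and 633 at 1.5-fold and 22 and 33 at 3-fold. An alternative chosen after seeing the data, 5 times the robust SD of genes of similar signal, gave 27 and 38. The lists of interferon-stimulated genes, cytokines, MHC class I, macrophage identity, oxidative stress and unfolded protein genes stayed apart from random lists under all 7 alternatives. These include centring, which could not move them. The interferon list moved inside their range with a further quantile normalisation (percentile 3.33), with members passing the filter only (3.78) and as a mean (11.004). The cell death list did so with averaged probe sets (97.4), unmatched lists (96.99) and as a mean (97.2), and MHC class II genes as a mean (97.1). As means, several lists came to stand apart: HuR-bound mRNAs (0.015), alternative activation (0.785), adhesion (2.48), neutrophils and mast cells (1.41) and reference genes (0.235, and 1.14 with averaged probe sets). The chemokine list turned from a median above 0 to a mean below it (percentile 0.0050), which Ccl2, Ccl7 and Ccl12 decide. Osteoclast genes turned upward when limited to members passing the filter (98.7). The mean of ribosomal proteins (-0.01) also differed in sign from their median of 0.01, and the mean of glycolysis genes was 0.06 against a median of 0.00. Ccl2 also weighs on the mean of the HuR-bound list. The cause of the remaining moves was not tested.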

Other observations

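The tests of separate places and of single places were chosen only after the result was seen. Several of the largest differences came from genes that lie side by side once genes that did not pass the filter are left out. This pattern was noticed in the gene list before it was tested. Neighbours outside the naming rule are therefore given here after their values were seen. The glutathione S-transferase genes Gstt1 (2.17), Gstt3 (1.41) and Gstt4 (4.55) were higher together with their neighbour Ddt (1.14), which encodes D-dopachrome tautomerase. Ltb (2.32), Lst1 (1.43) and Aif1 (1.37), immune genes of unrelated families, were higher together, while Tnf, which lies near them, differed by 0.31. Ptprn and Resp18, genes of secretory granules, were higher by 1.93 each, and Tmem176a (1.91) and Tmem176b (1.37) were higher as a pair. Gstt3, Gstt4, Ptprn and Resp18 had wildtype signals below the filter's floor. On the lower side stood Ccl2, Ccl7 and Ccl12, the lectin genes Clec4a2 (-2.60) and Clec4a3 (-2.09), and Sirpb1a (-1.91) and Sirpb1c (-2.21). Gm15056, also outside that rule, had the largest positive difference of all genes that passed the filter (3.40 against 8.09, difference 4.69), from a wildtype signal below the floor.

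In the order of genes that passed the filter, 16 neighbouring pairs differed at least 2-fold in the same direction, 8 higher and 8 lower. Random arrangements matched on signal gave a median of 2 pairs and at most 10 in 10000. Genes that did not pass may lie between the members of a pair, which may thus not be adjacent. Several pairs share a gene, however, so they make up 9 separate places, and random arrangements gave a median of 2 and at most 10 places (percentile 99.945). Chance positions are left open, because the pattern was noticed in these same genes, at least 1 random arrangement gave as many places, and genes between 1.5-fold and 2-fold, in which it had not been noticed, gave 45 places, inside the random range (percentile 62.0). Probes shared within a gene family stay open: 9 pairs have symbols that start differently (percentile 99.94), but 5 of these include clone-type symbols that do not show their family, and the 4 pairs left without them were inside the random range (percentile 93.1), a restriction added after the first count was seen. For a gain or loss of whole regions as the common cause, the other expressed genes within 5 genes of a pair were examined. Those that themselves differed by at least 2-fold were left out. The 87 genes kept had a signed median of 0.019 (95% bootstrap interval -0.01 to 0.11), below the bound of 0.3 set beforehand. This argues against such a common cause only for the genes kept, since leaving out the largest differences limits the test. At single places a gain or loss stays open. With the same genes left out, the interval lay wholly below that bound at 5 of the 9, but not at those of the Gstt, Aif1, Sirpb1 and Clec4a genes. Clec4n and Clec4e moved in the direction of their neighbours Clec4a2 and Clec4a3 (signed values 0.92 and 0.77). So did 2810408B13Rik (0.97) near Ctla2b, at 1 of the 5 places. Signed values are positive in the direction of the pair, which was lower at both places. A change limited to the pair itself is not excluded either. If the positions are not chance, a candidate explanation that remains is that the 2 cell populations, as separate lines, differ in how a few loci are used, which may or may not follow from the genotype; no second line of either genotype was analysed here to test it.

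Gene families read from symbol stems gave a negative result. Of 324 families with at least 5 genes passing the filter, 6 lay below the central 95% of matched random lists and 10 above it, where 16.2 in all would be so by chance. The family with the highest percentile was Cxcl (median 0.35 over 13 genes, percentile 99.975).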
